A study of Mus musculus with 6 samples.

How the data were processed

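The values were counts of unique molecular identifiers (UMIs) per gene and library, made by the authors, per the submitters' processing notes, from 3' reads of a QIAseq UPX kit placed on GRCm38. The aligner and counter are not given in the sources used here. The deposited table held 23265 genes in 6 libraries, and its metrics, read as other values, gave reads and UMIs per library. RNA came from miRNeasy columns after collagenase IV, dispase II and DNAse dissociation and sorting, per the submitters' protocol. Of 73570643 reads in the pool, 48.2% were used, 29.4% were not annotated and 8.79% were unmapped, with 4.97 reads per UMI. By library, 20.1% of reads were used in KC and 38.2% in RPM, against 49.3% to 57.5% elsewhere. Reads per UMI were 2.32 in KC and 4.79 to 5.41 elsewhere. Mitochondrially encoded genes took 5.03% of UMIs in KC and 14.0% in RPM, against 7.45% to 11.0% elsewhere. ERCC spike-in reads numbered 0. Gene identifiers matched GENCODE M21 with version for 97.3% of genes and without it for 99.97%.

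Counts were scaled by the trimmed mean of M values (TMM, edgeR 4.0.16 in R 4.3.3), giving factors of 0.883 for B cells, 0.778 for cDC1, 0.844 for cDC2, 1.01 for RPM, 1.47 for KC and 1.16 for LSEC. With all libraries thinned to 58547 UMIs the KC factor was 0.981, so it depended on depth. Ratios were taken between scaled counts with exact 95% Clopper-Pearson intervals conditional on the sum of both counts. There was 1 library per population and no test. A gene was called higher at 4-fold or more with the lower end of the interval at 2 or more and at least 10 UMIs in the higher library. Ratios to a count of 0 were given as "at least" the lower end of their interval, which lies below the ratio to a floor of 3 counts. Spearman's rho was taken over genes with at least 10 UMIs in either library. A gene was highest in a library if it was called by the same rule against the next highest library.

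Before the data were examined, 44 gene lists with 510 members were written from general knowledge, and 495 members were in the table. A member was measured at 10 counts in either library and called at 2-fold with an interval that left out 1. List medians used log2 ratios with a prior count of 2, and their percentile came from 10000 random lists matched on mean expression in 20 bins (seed 20240). Percentiles describe the list, since genes are not replicates. Named genes were the top 10 of each direction of each comparison and the top 6 of each library by the lower end of the interval. Predicted genes, immunoglobulin and T cell receptor segments, mitochondrially encoded, ribosomal protein and haemoglobin genes, Xist and Y-linked genes (8856 in all) were left out of that naming. Sort antigens, Evl and the 2 largest and 2 smallest members of each list were also named. Other list members, and the genes shared by 2 libraries, were chosen after their values were seen.

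Alternatives chosen beforehand were library totals, upper quartile and DESeq2 1.42.0 size factors, no count minimum or 30 counts, 99% intervals, prior counts of 0.5 and 5, thinning to the smallest library, and leaving out haemoglobin, immunoglobulin, mitochondrial and ribosomal protein genes. In a self-test, 25 genes per fold and direction were changed by 4-, 8-, 16- or 32-fold in Poisson counts drawn for the real genes at the real scaled library sizes. For KC against RPM, 16%, 56%, 64% and 72% were recovered when raised in KC and 12%, 48%, 64% and 72% in RPM, with 2 false calls. For KC against LSEC these were 8%, 40%, 52% and 64% and 16%, 32%, 44% and 68%, with 0 false calls. For cDC1 against cDC2, 64% and 40% were recovered at 4-fold, 100% and 96% at 8-fold and all above, with 3 false calls. For RPM against cDC2, 60% and 44% were recovered at 4-fold and all above, with 1 false call. Intervals held the true ratio for 98.7%, 98.6%, 97.5% and 97.6% of genes in that order. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.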

Results

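Gene expression was measured in 6 cell populations of mice that had received a systemic injection of a lentiviral vector carrying GFP under the PGK promoter. GFP-positive cells were sorted by flow cytometry and 1 RNA library was made per population. Each library was a pool of 3 animals. From the spleen came B cells, red pulp macrophages (RPM, the macrophages that clear aged red blood cells) and the classical dendritic cell types cDC1 and cDC2. From the liver came Kupffer cells (KC, the resident macrophages of the sinusoids) and liver sinusoidal endothelial cells (LSEC). The series asks which genes differ among the populations that such a vector reaches. With 1 library per population there was no replicate check and no test, so every ratio below compares 2 libraries and its 95% interval (exact Clopper-Pearson) covers counting error only.

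The table held 23265 genes and 7131620 unique molecular identifiers (UMIs, each marking 1 captured RNA molecule). Depth was 1118569 UMIs in B cells, 1321398 in cDC1, 2101556 in cDC2, 1109910 in RPM and 1421640 in LSEC. The KC library held 58547 UMIs, 0.821% of the total, and only 1036 genes reached 10 UMIs there, against 7489 to 9791 in the other 5 libraries. On the counts-per-million (CPM) scale, a single UMI was worth 17.1 in KC and 0.476 to 0.901 elsewhere. The KC library also differed in makeup: Gm42418, a gene model at chromosome 17, 39846958 to 39848788, that overlaps the annotated gene AY036118 by 923 bases, took 10.7% of its UMIs, against 0.682% to 1.60% in the others. Ribosomal protein genes took 16.8% of UMIs in B cells, 14% in cDC2 and 11.5% in cDC1, but 5.85% in RPM, 3.80% in LSEC and 3.22% in KC. Haemoglobin genes took 2.93% of UMIs in RPM and at most 0.167% in any other library.

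**Figure D1:**
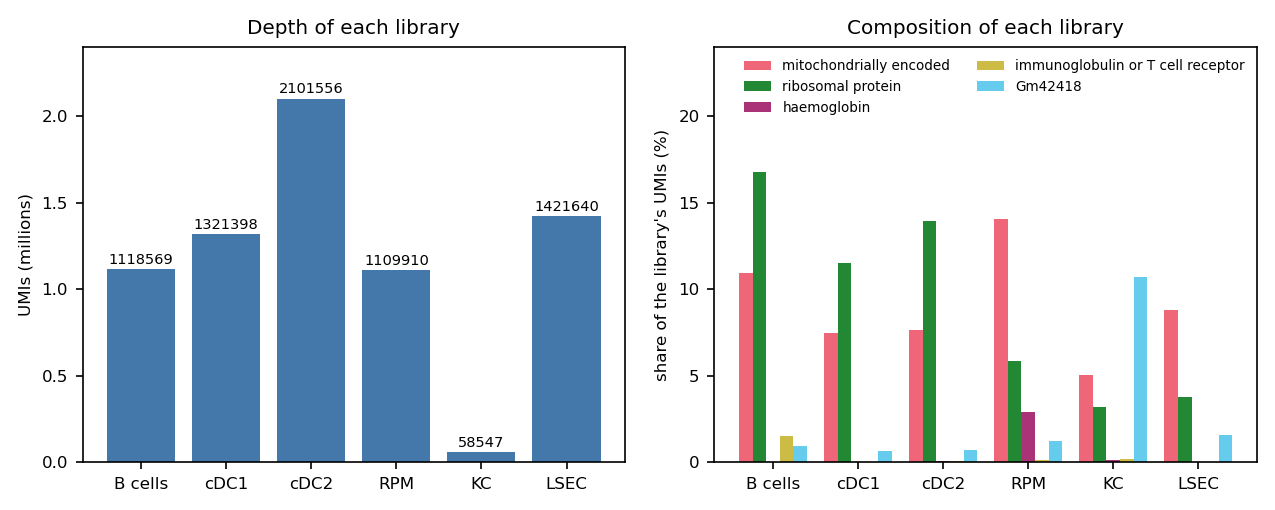
UMIs per library (first panel) and the share of each library's UMIs, in percent, taken by mitochondrially encoded, ribosomal protein, haemoglobin, immunoglobulin or T cell receptor genes and by Gm42418 (second panel). The KC library is the smallest at 58547 UMIs and has the largest share of Gm42418, 10.7%.

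The antigens used for sorting marked their populations, apart from CD45 in KC. Cd19 (chromosome 7, 126408450 to 126414889; all positions are GRCm38), the B cell gate, stood at 467 scaled CPM in B cells and between 0 and 15.2 elsewhere. Pecam1, which encodes CD31, stood at 364 in LSEC and between 23.2 and 105 in the other 5 libraries. Cd8a stood at 251 in cDC1 and 7.89 in cDC2, and Itgam, which encodes CD11b, at 25.4 in cDC2 and 1.95 in cDC1. Itgax, which encodes CD11c, was highest in cDC2 at 154 and in cDC1 at 95.4, with 55.4 in RPM and 57.9 in KC (5 UMIs). Adgre1, which encodes F4/80, stood at 429 in RPM, 232 in KC (from 20 UMIs) and at most 62.6 elsewhere. Ptprc, which encodes CD45, was lowest in LSEC at 27.9, the CD45-negative sort, next lowest in KC at 220.2 (19 UMIs), and highest in cDC2 at 1517. If the share of B cell markers found in KC (0.511%) held for all genes, it would give 25.8 Ptprc UMIs there. The submitters' description of the B cell library names B220, a splice form of CD45, where the protocol names CD19; gene counts cannot tell splice forms apart.

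**Figure D2:**
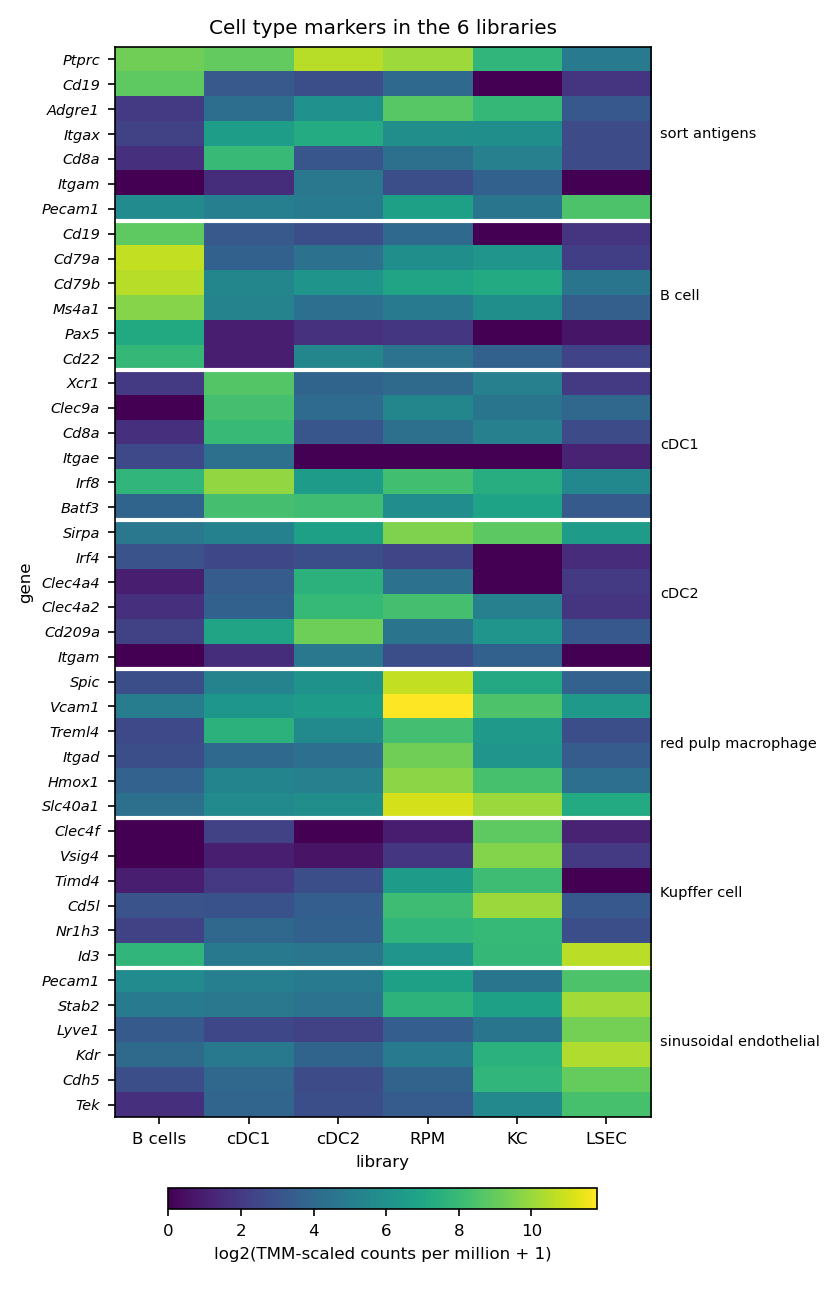
Heat map of log2(TMM-scaled CPM + 1) for the sort antigens and the first 6 members of 6 preset marker lists (rows) in the 6 libraries (columns). Cd19 stands at 467 scaled CPM in B cells, Pecam1 at 364 in LSEC and Cd8a at 251 in cDC1.

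Kupffer cells and red pulp macrophages were sorted through the same CD45 and F4/80 gate, so setting KC against RPM compares resident macrophages of liver and spleen. Some genes of the Kupffer cell identity were far higher in KC. Vsig4, a complement receptor of the immunoglobulin superfamily (ENSMUSG00000044206.3, chromosome X, 96247203 to 96293438), had 67 UMIs against 3 and was 289.6-fold higher (94.9 to 1439.5). Clec4f, a lectin receptor that defines Kupffer cells in mice (chromosome 6, 83644542 to 83656187), was 532-fold higher (90.2 to 21504) from 41 UMIs against 1. The chemokine receptor gene Ccr5 (chromosome 9, 124121543 to 124147699) was 90.8-fold higher (46.5 to 198). RPM in turn had higher levels of several genes for recycling iron and haem, and of others that mark it: Ftl1, the ferritin light chain, was 22.4-fold higher in RPM (16.9 to 30.3), Spic, the transcription factor that red pulp macrophages require (chromosome 10, 88674772 to 88685015), 12.3-fold (7 to 23.8), and the adhesion molecule gene Vcam1 (chromosome 3, 116109949 to 116129688) 10-fold (7.06 to 14.8).

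Of 10 measured Kupffer cell markers, 6 were at least 2-fold higher in KC with an interval above 1 and 2 were higher in RPM, with a median log2 ratio of 1.63. That median was above all of 10000 random lists of the same size matched on expression, whose typical median was -0.45. It was 0.94 with the share of the LSEC library found in KC (0.523%) taken off. With the share of B cell markers found in KC (0.511%) taken off for all other libraries, it was 0.85. Marco, a scavenger receptor gene, was 10.2-fold higher (7.07 to 14.7), whereas C6, a terminal complement component gene, was 2.31-fold (1.43 to 4.00) and Clec1b 2.17-fold higher in RPM (1.16 to 4.57). The ficolin gene Fcna was 1.87-fold higher in RPM (1.46 to 2.45), short of the 2-fold bound. Of 10 red pulp macrophage markers, 8 were higher in RPM and 0 in KC (median -2.14, percentile 0.06); the iron exporter gene Slc40a1 was 2.03-fold higher in RPM (1.64 to 2.53) and Hmox1, which encodes the haem-degrading enzyme, 2.54-fold (1.76 to 3.81). Haem and iron handling genes followed the same direction, with 9 of 14 higher in RPM, 1 higher in KC (Nfe2l2, 2.11-fold, 1.08 to 3.81) and a median of -1.67 (percentile 0.0500). The biliverdin reductase gene Blvrb was 13.3-fold higher in RPM (6.07 to 36.2). All 6 erythroid genes that differed were higher in RPM (median -4.05 over 10, below all random lists, but -1.23 with the 4 genes at a count of 0 set to their bound, against -1.20 in random lists), led by Hbb-bt at 39.7-fold (20.9 to 86.9) and Hba-a1 at 35.6-fold (25.7 to 50.9), so red cell transcripts moved with the iron genes in the RPM library. The nearly identical copies Ftl1 and Ftl1-ps1 (42.1-fold higher in RPM), and Hba-a1 and Hba-a2, may share reads, and their single values are uncertain.

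Of 14 macrophage core markers, 7 were higher in RPM, 1 in KC and 6 in neither (median -1.20, percentile 1.59, or -0.66 by library totals). Csf1r, the receptor for the macrophage growth factor, was 6.26-fold higher in RPM (3.84 to 11.0) and Cd68 5.01-fold (3.23 to 8.23), while the lysozyme gene Lyz2 was 3.4-fold higher in KC (2.00 to 5.56) and the complement gene C1qa 1.77-fold (1.54 to 2.04), short of the 2-fold bound. Complement components divided, with 4 of 9 higher in RPM and 1 in KC (median -1.20, percentile 7.90). C4b was 56.2-fold higher in KC (15.4 to 307) and the properdin gene Cfp 3.04-fold higher in RPM (2.37 to 3.94). Fc and complement receptors also divided, with 3 of 8 higher in RPM, among them Fcgr3 at 9.38-fold (3.19 to 45.7). In KC 2 were higher, Vsig4 and Fcgr2b (3.54-fold, 2.28 to 5.34), and the list median was -0.67 (percentile 8.98). Fcgr2b had 30 UMIs in KC, below the 33.0 that the share of B cell markers found there (0.511%) would give. With the share of the LSEC library found in KC (0.523%) taken off, the list median was -1.98.

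Several groups stood above their random lists in KC. Scavenger receptors had 6 of 14 members higher in KC and 2 in RPM (median 0.51, percentile 99.3), with Msr1 10.3-fold higher in KC (5.32 to 19.6) and the phagocytic receptor gene Mertk 3.41-fold higher in RPM (1.78 to 7.51). The MHC class II presentation list had a median of 0.60 (percentile 99.6) with 2 of 11 members higher, H2-Ab1 at 2.03-fold (1.72 to 2.37) and the class II transactivator gene Ciita at 3.50-fold (1.55 to 7.19). Interferon-stimulated genes had a median of 0.58 (percentile 99.1): 3 of 15 were higher in KC, such as Ifit2 (6.48-fold, 2.21 to 17.2), and 2 in RPM, such as Ifi27l2a (2.70-fold, 1.92 to 3.92). That median turned to -0.47 with at least 30 counts and to -0.59 with all libraries thinned to the smallest. Chemokine receptors (median 1.12, percentile 99.9) divided between Ccr5 in KC and Ccr3, which was 11.7-fold higher in RPM (3.97 to 56.8). Costimulation genes stood at a median of 1.03 (percentile 99.6) though 0 of 9 passed in KC and 1, Cd86, was 2.96-fold higher in RPM (1.54 to 6.54). Endothelial markers moved with these groups: 7 of 15 sinusoidal endothelial genes were higher in KC and 1 in RPM (median 1.36, above all random lists), with Cdh5, the endothelial cadherin gene, 17.6-fold higher in KC (8.37 to 37.9) and the VEGF receptor gene Kdr 6.69-fold (3.42 to 12.6). So did the coagulation list (median 1.45, percentile 99.8), led by F8 at 4.99-fold (1.39 to 14.9). The share of the LSEC library that LSEC-restricted genes show in KC (0.523%) was also taken off. The coagulation median was then 0.11 and the sinusoidal endothelial median -2.79, which is low by construction. The scavenger receptor median was then -0.36, in the other direction. With at least 30 counts and nothing taken off, it was -0.26. If the share of B cell markers found in KC (0.511%) held for all genes, the class II gene H2-Aa would have 247 UMIs there. It had 186, and F8 had 5 against 10.2. With that share taken off, medians were 0.02 for chemokine receptors, 0.28 for costimulation and 0.45 for interferon-stimulated genes. An even share at this rate is argued against below.

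By the fixed rule for single genes (at least 4-fold, interval above 2, at least 10 UMIs), genes higher in KC than in RPM numbered 57 of 8759 compared, and genes higher in RPM than in KC numbered 184. The other named genes higher in KC were Mat1a (311-fold, 50.7 to 12797), which encodes the hepatic S-adenosylmethionine synthetase, Itgal, Emilin2, Pmp22 and St3gal5 (14.5-fold, 8.88 to 23.7). In RPM they were the protease inhibitor gene Slpi (14.7-fold, 8.6 to 27.7), the transferrin gene Trf (9.25-fold, 6.04 to 15.0), Mpp6, the prostaglandin D synthase gene Hpgds and Gpr65. The KC counts of the 10 genes named as higher in RPM were 0.173 to 1.38 times what the share of B cell markers found in KC would give (Spic 12 UMIs against 10.7), so the size of these folds is uncertain. The libraries correlated across genes with Spearman's rho of 0.634. Which population had more such genes depended on the scaling: by library totals, which move the median of all genes by 0.52 on the log2 scale, 117 genes were higher in KC and 64 in RPM, and with the LSEC share taken off, 44 and 280.

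**Figure D3:**
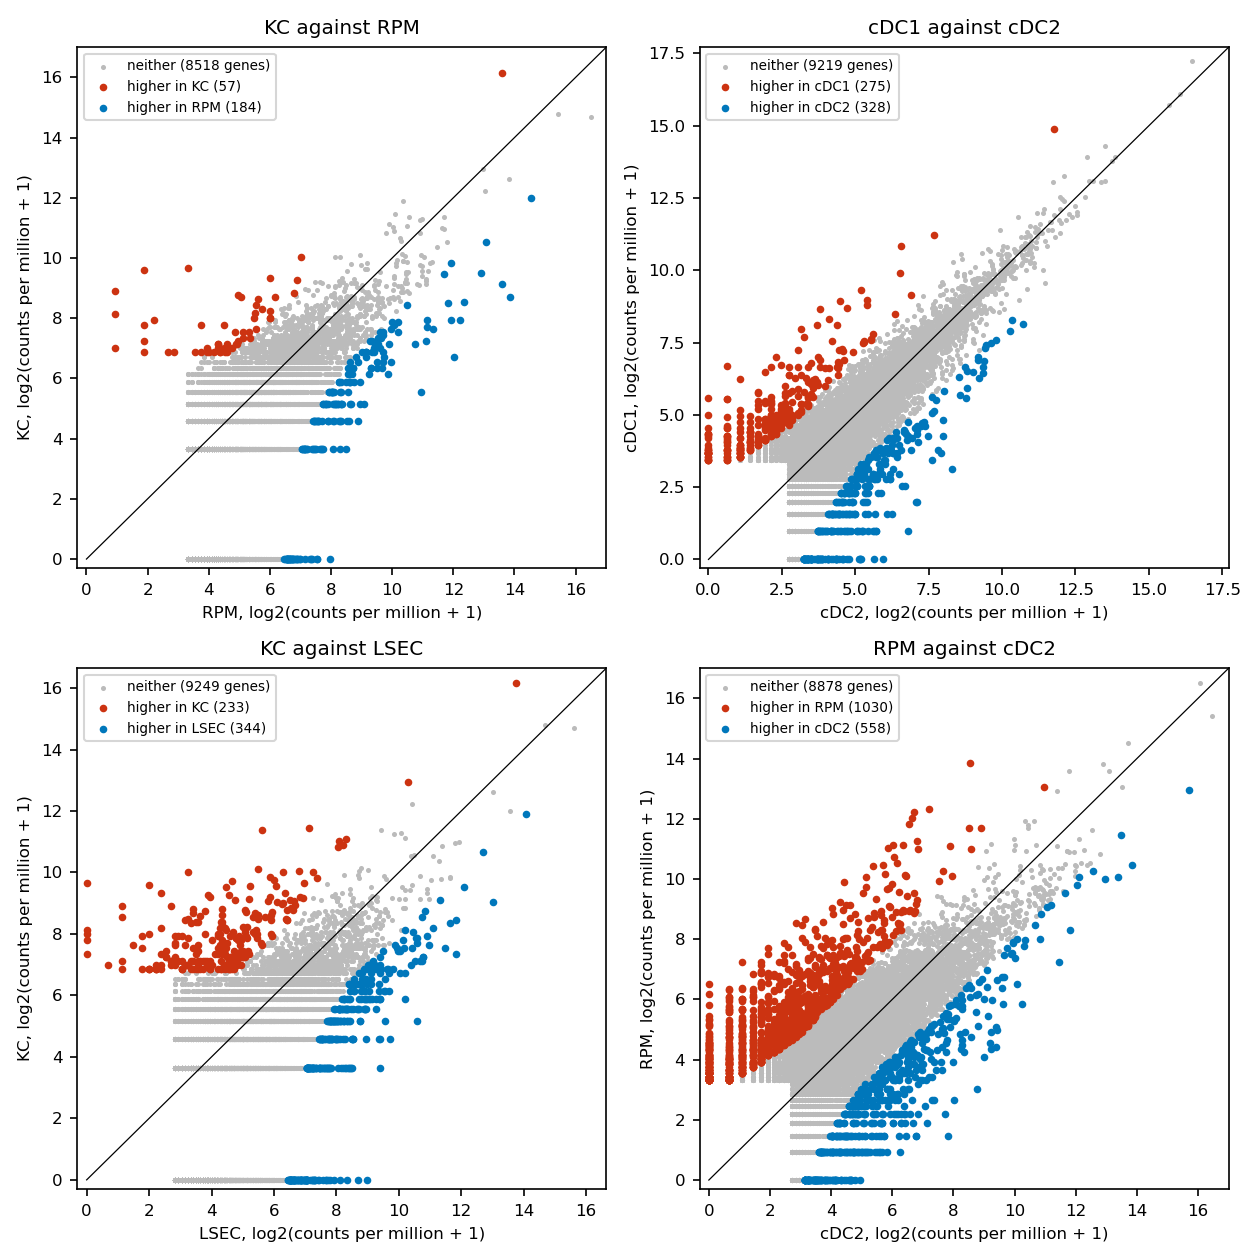
Expression of each gene in the libraries of the 4 pairwise comparisons, as log2(TMM-scaled CPM + 1), 1 point per gene, with genes that differ by the fixed rule in colour. KC against RPM has 57 and 184 such genes, cDC1 against cDC2 275 and 328, KC against LSEC 233 and 344, and RPM against cDC2 1030 and 558.

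The dendritic cell subsets of the spleen, cDC1, which presents antigen from dead cells to CD8 T cells, and cDC2, which mainly primes CD4 T cells, were the most alike of the 4 pairs compared (rho 0.821 across genes). Their identity genes still parted sharply. In cDC1, the chemokine receptor gene Xcr1 (chromosome 9, 123852315 to 123862029) was 31.4-fold higher (20.6 to 50.0), the sort antigen Cd8a (chromosome 6, 71373427 to 71379173) 31.8-fold (18.6 to 59.0), the adhesion molecule gene Cadm1 23.1-fold (16.6 to 33.0) and Naaa, a lipid amidase gene, 19.8-fold (16.9 to 23.4). In cDC2, the lectin genes Clec4a4 (chromosome 6, 122990367 to 123024105) and Clec4a2 were 20.1-fold (10.8 to 42.2) and 20.5-fold higher (11.6 to 40.0), and the short-chain fatty acid receptor gene Ffar2 17.9-fold (10.4 to 34.0).

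Of 12 cDC1 markers, 11 were higher in cDC1 and 0 in cDC2 (median log2 ratio 4.00, above all random lists). The exception was the transcription factor gene Batf3 at 1.13-fold (0.981 to 1.30). Of 12 cDC2 markers, 8 were higher in cDC2 (median -1.70, below all random lists), with the gate antigen Itgam at 13-fold (3.41 to 111), and 1, Tnfaip2, was 7.94-fold higher in cDC1 (2.95 to 26.7). Plasmacytoid dendritic cell markers were higher in cDC1 in 6 of 8 cases (median 1.72, above all random lists), with the lectin gene Siglech at 14.7-fold (7.60 to 31.7) and Ccr9 at 10.4-fold (5.84 to 19.7). Sinusoidal endothelial and coagulation genes had medians of 0.63 (percentile 99.4) and 1.77 (percentile 99.95), with 2 of 13 and 3 of 5 members higher in cDC1 and 0 in cDC2. Over 13 LSEC markers, cDC1 held 1.30% of the LSEC UMIs (1.14 to 1.47) and cDC2 1.52% (1.35 to 1.70). Their libraries held 1321398 and 2101556 UMIs. A near-equal share of LSEC RNA would raise such genes in the smaller library, so the endothelial median need not be a trait of cDC1. Ece1, an endothelin-converting enzyme gene of the coagulation list, was 4.32-fold higher in cDC1 (3.33 to 5.67). NK cell markers went the other way (median -1.97, percentile 1.58), with 3 of 4 higher in cDC2, among them the granzyme gene Gzma at 21.4-fold (5.73 to 180.3), from 2 UMIs against 74.

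Innate response genes differed in detail. Interferon-stimulated genes were higher in cDC2 in 9 of 16 cases and in cDC1 in 1 (median -1.23, percentile 0.0100). Oas1a had 0 UMIs in cDC1 and 107 in cDC2, at least 16.5-fold by the lower end of the interval, Oasl2 was 15.6-fold higher in cDC2 (4.13 to 132), and Mx1 was 3.02-fold higher in cDC1 (1.70 to 5.52). Inflammatory cytokines and chemokines divided, with 5 of 10 higher in cDC2, such as Ccl3 at 6.31-fold (3.19 to 14.2) and Ccl5 at 3.74-fold (3.46 to 4.04), and 3 higher in cDC1, the interleukin 12 subunit gene Il12b at 13.7-fold (7.65 to 26.5), Cxcl9 at 10.7-fold (8.35 to 13.9) and Cxcl10 (median -1.14, below all random lists). Fc and complement receptors had a median of -1.14 (percentile 1.43), with Fcer1g 5.94-fold higher in cDC2 (5.26 to 6.72). Among nucleic acid sensors, Tlr3 was 5.99-fold higher in cDC1 (3.55 to 10.6) while Tlr7 was 2.72-fold (1.36 to 6.05) and Tmem173, which encodes STING, 3.01-fold higher in cDC2 (1.95 to 4.83). Chemokine receptors had 4 of 10 members higher in cDC1 and 1, Ccr6, in cDC2 (median 0.76, percentile 99.9). MHC class II transcripts stood at about the same level in both subsets: 9 of 11 MHC class II genes passed in neither direction, 1 was higher in each, and the median was 0.03, or -0.08 by library totals. Dissociation stress genes had a median of -0.56 (percentile 0.540), although 12 of 15 passed in neither direction, and 3 were higher in cDC2, such as Atf3 at 6.66-fold (2.43 to 25.5) and Hspa1b at 4.79-fold (2.56 to 9.94).

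Genes higher in cDC1 than in cDC2 numbered 275 of 9822, and genes higher in cDC2 than in cDC1 numbered 328. The remaining named genes in cDC1 were P3h2 (181-fold, 31.8 to 7224), Ttc39a, Gpr141b, Pdia5, Rab7b (24.5-fold, 14.5 to 44.6) and the mannose 6-phosphate receptor gene Igf2r, at 32 UMIs against 0. In cDC2 they were Sirpb1a (40.3-fold, 20.3 to 93.9), the ryanodine receptor gene Ryr3 (112-fold, 19.9 to 4463), the elastase gene Mmp12 (45.4-fold, 15.3 to 222), Scn3a, Pla2g7 and Cass4. Sirpb1a and the Clec4a genes lie in families of similar copies, so their single values are uncertain. Library totals move the median of all genes in this pair by -0.11.

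Setting KC against LSEC compares macrophages and endothelial cells of the liver, the populations that line the same sinusoids. Several macrophage genes were far higher in KC. Ccr5 had 70 UMIs against 0 and was at least 354-fold higher by the lower end of its interval. Timd4, a receptor for phosphatidylserine on dying cells, had 24 against 0 and was at least 115-fold higher. Clec4f was 392-fold (102 to 3347), Vsig4 256-fold (105 to 815) and Cd5l, a secreted macrophage protein gene, 123-fold higher (69.6 to 234). In LSEC, Gpihbp1, which anchors lipoprotein lipase to capillary walls (chromosome 15, 75596628 to 75599481), was 22.6-fold higher (13.5 to 41.3), the clotting factor VIII gene F8 (chromosome X, 75172715 to 75382615) 20.4-fold (8.72 to 62.8), Igfbp7 15.8-fold (11.8 to 21.6) and the endothelial phosphatase gene Ptprb 15.6-fold (9.57 to 27.2). Lpl, the lipase that Gpihbp1 binds, was 306-fold higher in KC (78.1 to 2636), from 32 UMIs against 2.

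Of 11 Kupffer cell markers, 8 were higher in KC and 2 in LSEC (median log2 ratio 5.01, above all random lists); those in LSEC were the BMP target gene Id3 at 6.61-fold (4.27 to 10.8) and Clec1b at 4.04-fold (2.18 to 8.45). Macrophage core genes were higher in KC in 9 of 13 cases and in LSEC in 2 (median 3.10), with C1qa at 55.4-fold (42.8 to 72.6) in KC, and the mannose receptor gene Mrc1 2.72-fold (2.11 to 3.56) and Maf 2.95-fold (2.27 to 3.92) higher in LSEC. Complement components were higher in KC in 7 of 10 cases (median 3.71), among them Cfp at 20.4-fold (14.1 to 29.4), and factor H, Cfh, was 4.13-fold higher in LSEC (1.75 to 12.8). The MHC class II list was higher in all 11 members (median 2.70, above all random lists), from 3.70-fold for H2-Oa (1.26 to 9.01) to 38.3-fold for Ciita (11.9 to 143). H2-Aa (186 UMIs in KC), Cd74 (684) and H2-Oa (6) lay below the 247, 960.5 and 7.80 that the share of B cell markers found in KC would give. Lineage markers of other blood cells moved with it: 4 of 5 B cell genes (median 2.23) and 4 of 5 erythroid genes (median 2.76) were higher in KC. So were 4 of 4 B cell receptor signalling genes (median 3.45), such as Cd79b at 6.54-fold (3.2 to 12.6) and Syk at 38.3-fold (11.9 to 143). The share of B cell markers found in KC would give 90.5 UMIs of Hba-a1, which had 36, and 9.15 of Cd79b, which had 13. With that share taken off, medians were 0.73 for B cell, -4.07 for erythroid and 2.57 for B cell receptor signalling genes. The share came from B cell markers themselves, so it cannot judge the B cell list. An even share at this rate is argued against below.

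All 16 sinusoidal endothelial markers were higher in LSEC (median -3.25, below all random lists), from Cdh5 at 2.32-fold (1.48 to 3.88) to Lyve1, a hyaluronan receptor gene, at 28.1-fold (7.77 to 233) with Gata4 and Tie1 at 0 UMIs in KC. Dnase1l3 still had 328 UMIs in KC against 28476 in LSEC. Other vascular genes (median -2.42, percentile 0.0400), coagulation genes (median -2.22, percentile 1.22) and the BMP and TGF-beta pathway (median -1.37, percentile 0.960) were also lower in KC, with 5 of 9, 4 of 6 and 6 of 12 members higher in LSEC and 0 in KC in each list. Bmp2, which sinusoidal endothelium secretes, was 10.5-fold higher in LSEC (4.08 to 38.6), its coreceptor gene Eng 7.97-fold (4.19 to 17.5), and the Fc receptor gene Fcgr2b, by which LSEC take up immune complexes, 10.4-fold (7.28 to 15.4). Scavenger receptors divided between the populations, with Marco (153-fold, 69.6 to 398) and 3 others higher in KC, and Stab2 (11.3-fold, 5.91 to 24.6) and 4 others higher in LSEC (median -0.62, percentile 47.6).

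Genes higher in KC than in LSEC numbered 233 of 9826, and genes higher in LSEC than in KC numbered 344, with a rho of 0.547 across genes. The other named genes in KC were Klra2, Itgal and Myof, each with 0 UMIs in LSEC, and in LSEC Ccdc152 (44.5-fold, 15.2 to 216), Cavin2 (0 UMIs in KC, at least 11.7-fold), Mgll (0 UMIs in KC, at least 9.72-fold), Sptbn1, Plxnc1 and Nostrin (28.9-fold, 7.99 to 239). KC counts of the 10 genes named as higher in LSEC were 0 to 0.636 times that share, so the size of these folds is uncertain as well. By library totals, which move the median of all genes by 0.33, genes higher in KC than in LSEC numbered 268 and those higher in LSEC 197.

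RPM and cDC2 set macrophages against dendritic cells within the spleen, and no list that defines these cells changed its direction with the scaling. RPM had far higher levels of iron, complement and scavenger receptor genes: Vcam1 was 39.2-fold higher (33.5 to 46.1), the ferroportin gene Slc40a1 (chromosome 1, 45908068 to 45926523) 37.1-fold (30.4 to 45.8), the endosomal metal transporter gene Slc11a1 60.1-fold (33.2 to 121) and the growth factor gene Igf1 46.7-fold (33.5 to 67.0). cDC2 had higher levels of MHC class II genes. Among single genes, the lectin gene Cd209a (chromosome 8, 3743397 to 3748984) was 26.1-fold higher (17.6 to 40.6), the oxysterol receptor gene Gpr183, which positions cDC2 in the spleen, 59.5-fold (23 to 219), and Ffar2 127-fold (34.9 to 1051).

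All 10 red pulp macrophage markers and all 8 Kupffer cell markers measured were higher in RPM (medians 4.51 and 4.25), as were 12 of 14 macrophage core genes (median 4.36), with Lyz2 the exception at 6.25-fold higher in cDC2 (4.96 to 7.96). Haem and iron genes were higher in RPM in 12 of 14 cases (median 2.87), scavenger receptors in 12 of 13 (median 3.06; Mertk 48.5-fold, 28.1 to 91.9; Cd163, the haemoglobin scavenger receptor gene, 38.5-fold, 18.3 to 97.2), complement components in 7 of 9 (median 4.12; C1qc 22.1-fold, 19.1 to 25.6). The same held for lipid handling genes in 10 of 12 (median 1.96; the liver X receptor gene Nr1h3 18.5-fold, 11.8 to 30.4) and lysosome genes in 11 of 14 (median 1.68; cathepsin D, Ctsd, 13.3-fold, 11.2 to 15.8). Each of these medians lay at or above the 99.9 percentile of its random lists. Immunoregulatory macrophage genes were higher in RPM in 4 of 5 cases (median 2.76), with Il1rn higher in cDC2. Erythroid genes moved with them, since all 10 were higher in RPM (median 4.16), Hba-a1 by 39.9-fold (36.9 to 43.2), as did 8 of 15 sinusoidal endothelial genes (median 1.00, percentile 98.9), such as Stab2 at 8.94-fold (6.34 to 12.9), and 8 of 12 B cell receptor signalling genes (median 1.26), such as Bank1 at 6.70-fold (5.23 to 8.66). Over the same 13 LSEC markers, chosen for low counts in other libraries, RPM held 2.25% of the LSEC UMIs and cDC2, the larger library, 1.52%. How much of the endothelial median an even share of LSEC RNA would give was not tested.

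In cDC2, 10 of 11 MHC class II genes were higher (median -2.77, below all random lists), with H2-Aa at 10.3-fold (9.75 to 10.8) and H2-Oa at 13-fold (9.73 to 17.8), as were 7 of 8 pan-dendritic genes (median -2.16), such as Flt3, the growth factor receptor gene of dendritic cells, at 24-fold (8 to 118). Costimulation and maturation genes were higher in cDC2 in 6 of 11 cases (median -1.80, percentile 0.0200), Icosl by 8.36-fold (5.30 to 13.9), while Cd86 was 4.46-fold higher in RPM (3.62 to 5.52). Cell cycle genes were higher in cDC2 in 9 of 13 cases and in RPM in 0 (median -1.27, percentile 0.0200), with Tyms at 6.84-fold (3.87 to 13.2) and Birc5 at 6.23-fold (3.72 to 11.2). Monocyte genes (median -2.30, percentile 0.1) included Ly6c2 at 38.5-fold (6.65 to 1545), and the chemokine gene Ccl5 was 18.7-fold higher in cDC2 (16 to 21.9). Of 12 cDC2 markers, 6 were higher in cDC2 and 2 in RPM, namely Tnfaip2 at 40.3-fold (16.8 to 126) and Sirpa, the signal regulatory protein gene often used to mark cDC2, at 7.13-fold (6.07 to 8.41; median -1.14, percentile 2.43). Nucleic acid sensors were higher in RPM in 7 of 15 cases and in cDC2 in 1 (median 0.92, percentile 99.6), with Tlr8 at 22.6-fold (8.35 to 85.7) and Tmem173 3.15-fold higher in cDC2 (2.06 to 5.01).

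Genes higher in RPM than in cDC2 numbered 1030 of 10466, and genes higher in cDC2 than in RPM numbered 558 (rho 0.675). The remaining named genes in RPM were Sned1 (100 UMIs against 0, at least 42.2-fold), Cela1, the erythroid nuclear protein gene Hemgn (80 against 0, at least 33.6-fold), Paqr9, Ccr3 (51.4-fold, 30.3 to 94.8) and Slpi (34.8-fold, 28.8 to 42.4). In cDC2 they were Pglyrp1 (60.6-fold, 30.6 to 141), Klrd1, Cd7 (32.4-fold, 21.5 to 51.4), Ppp1r14a, Slamf7 (30.2-fold, 19.8 to 48.4), Jaml and Tmem176b (21.7-fold, 16.9 to 28.3). By library totals, which move the median of all genes by 0.23, genes higher in RPM than in cDC2 numbered 1286 and genes higher in cDC2 than in RPM numbered 404.

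**Figure D4:**
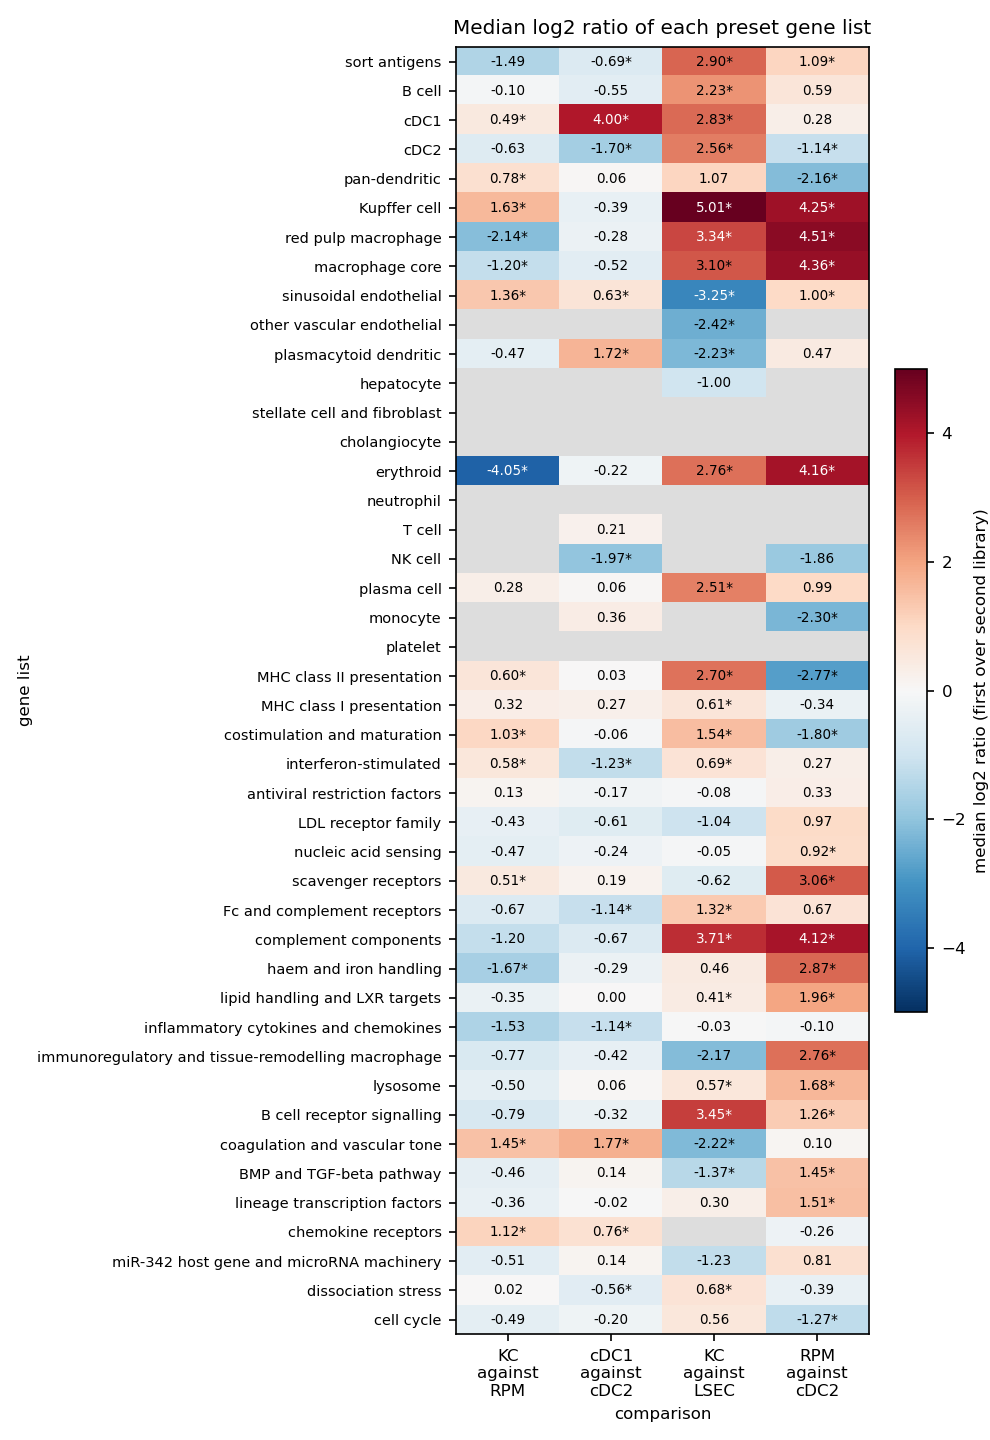
Heat map of the median log2 ratio of each preset gene list (rows) in the 4 pairwise comparisons (columns), with a star where the median lies among the lowest or highest 2.5% of 10000 random lists matched on expression and grey where fewer than 3 members were measured. The red pulp macrophage list stands at -2.14 in KC against RPM and 4.51 in RPM against cDC2.

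Across all 6 libraries, each population had genes at least 4-fold above the next highest library. LSEC had the most: genes highest in LSEC numbered 494, led by Calml4, Phldb2, Ctdspl, the caveolar gene Cavin2 (37.4-fold above RPM, 22.6 to 67.2), Plxna2 and the guidance receptor gene Robo4. Genes highest in B cells numbered 176, with the B lineage transcription factor gene Pax5 54-fold above RPM (18.1 to 265), Cd19 30.7-fold (19.0 to 53.2), the surrogate light chain gene Vpreb3 53.0-fold (20.3 to 196), Chchd10, Lipc and Ablim1. Genes highest in RPM numbered 136, among them the glutamate transporter gene Slc1a3 (41.6-fold above cDC2, 15.8 to 156), Sgip1, Dgki, Tgm1, Ubd and the high-affinity Fc receptor gene Fcgr1 (21.1-fold above cDC2, 11.1 to 45.0). Genes highest in cDC2 numbered 58, led by Ryr3 (61.2-fold above RPM, 16.7 to 509), Gsg1, Clec4a4, Scn3a, Pglyrp1 and Tctex1d2. Genes highest in cDC1 numbered 56, among them the interferon-inducible gene Ifi205 (16.5-fold above cDC2, 12.1 to 22.9), Gpr141b, Rab7b, Ttc39a, Il12b and the cystatin gene Cst3, which had 31394 UMIs and was 8.76-fold above cDC2 (8.52 to 9). Genes highest in KC numbered 25, led by Vsig4 (256-fold above LSEC, 105 to 815), Clec4f (122-fold above cDC1, 44.2 to 469), Ccr5 (64.1-fold above cDC1, 35.2 to 126), Emilin2, Etl4 and C4b. By the highest value alone, the shares over 12317 genes were 24.1% in LSEC, 19.8% in B cells, 15.8% in RPM, 14.4% in KC, 13.6% in cDC2 and 12.4% in cDC1. They cannot be judged against an equal share of 16.7%, since they depend on depth and scaling. In KC 1 UMI was worth 11.6 scaled CPM, above the 10.1 of 10 UMIs in B cells. Without the KC library, genes highest in RPM numbered 309 and genes highest in LSEC numbered 794.

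Genes shared by 2 populations and at least 4-fold above the remaining 4 libraries were found for most pairs. Each gene needed at least 10 UMIs in both libraries of the pair. Genes at that count numbered 1036 in KC, 8749 in RPM and 9791 in LSEC. The numbers for pairs with KC therefore cannot be set beside those of other pairs. RPM and KC shared 43 such genes, among them C1qa, C1qb, C1qc, Fcna, Slc40a1, Mafb, Cd5l, Paqr9 and Hmox1. The dendritic cell types shared 52, including Flt3, Slamf7, Jaml and the lipoxygenase-activating gene Alox5ap, and cDC2 shared 20 with RPM, including Clec4a2. RPM and LSEC, from different organs, shared 53, including Myo10 and Kitl, which encodes stem cell factor. KC and LSEC shared 13, all named genes, among them the endothelial genes Cdh5, Kdr, Stab1 and Col4a1. The KC counts of Cdh5 and Kdr were 2.25% (1.36 to 3.52) and 0.713% (0.407 to 1.16) of those in LSEC, against 0.523% over 75 LSEC-restricted genes. LSEC RNA in the KC library could thus give the whole Kdr count, but not that of Cdh5 at this share. B cells and LSEC shared 20, including the sphingosine receptor gene S1pr1 and Gimap1.

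Lists that bear on how a cell meets a vector were compared in the same way. All libraries came from GFP-positive cells of injected mice, with none from GFP-negative cells or from mice without vector. The ratios therefore cannot show what lets a vector in or what follows its entry. Lrp1, a large endocytic receptor gene of the LDL receptor family, the family through which the common lentiviral envelope enters cells, was 41.8-fold higher in KC than in LSEC (22.6 to 81.0) and 16.8-fold higher in RPM than in cDC2 (11.0 to 26.7). The family as a whole had a median of 0.97 in RPM against cDC2 (3 of 6 higher), -1.04 in KC against LSEC (1 of 5 higher in each direction) and -0.43 in KC against RPM with 0 of 6 passing. Antiviral restriction genes passed in 0 of 15 cases between KC and RPM (median 0.13). The membrane restriction genes Ifitm1 and Ifitm3 were 34.2-fold (9.26 to 286) and 4.58-fold (3.95 to 5.34) higher in cDC2 than in cDC1. Of 13 antiviral restriction genes in that pair, 10 passed in neither direction, 2 were higher in cDC2 and 1 in cDC1 (median -0.17). The LDL receptor family had a median of -0.61 there, with 1 of 6 higher in cDC2. Ifitm2 was 4.67-fold higher in LSEC than in KC (3.51 to 6.37), where Samhd1, whose product depletes nucleotides, was 6.38-fold higher in KC (4.13 to 9.6). MHC class I presentation had medians of 0.32 in KC against RPM (percentile 96.9), 0.27 in cDC1 against cDC2 (92.9), 0.61 in KC against LSEC (98.8) and -0.34 in RPM against cDC2 (63.0). In those pairs 10, 8, 10 and 8 of 11 members passed in neither direction, and 3 were higher in cDC2 than in RPM. Nucleic acid sensors had medians of -0.47 in KC against RPM and -0.05 in KC against LSEC, and both turned positive by library totals (0.07 and 0.28).

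Lipid handling genes had a median of -0.35 in KC against RPM (0.20 by library totals) and 0.41 in KC against LSEC (-0.23 with at least 30 counts), where 5 of 12 were higher in KC, such as Pltp, a phospholipid transfer protein gene, at 115-fold (25.6 to 1056). Lysosome genes stood at -0.50 in KC against RPM (0.04 by library totals) and 0.57 in KC against LSEC, with the cathepsin gene Ctsb 3.88-fold higher in KC (3.35 to 4.47). Lineage transcription factor genes divided by population: Irf8 was 10.6-fold higher in cDC1 than in cDC2 (9 to 12.7), Mafb 33.2-fold higher in KC than in LSEC (18.3 to 61.8) and Pparg 39.2-fold higher in RPM than in cDC2 (19.5 to 92.1). Plasma cell genes had a median of 2.51 in KC against LSEC, from 4 UMIs each of Jchain and Mzb1 in KC. Of 14 hepatocyte genes, 12 passed in neither direction in KC against LSEC (median -1, percentile 37.4, or 0 with genes at a count of 0 set to their bound), with Alb 8.77-fold higher in LSEC (2.98 to 42.6), from 3 UMIs against 503. T cell genes had enough measured members for a median only in cDC1 against cDC2 (0.21 over 4), where Cd8b1 had 23 UMIs against 0. By library totals the median changed sign in further lists: B cell, plasmacytoid dendritic, LDL receptor family, BMP and TGF-beta, lineage transcription factor and microRNA genes in KC against RPM; pan-dendritic, plasma cell, lipid and lysosome genes in cDC1 against cDC2; antiviral restriction and inflammatory genes in KC against LSEC; and inflammatory genes in RPM against cDC2 (-0.10 and 0.15). By DESeq2 size factors it did so for dissociation stress genes in KC against RPM (0.02 and -0.02) and lineage transcription factors in cDC1 against cDC2 (-0.02 and 0.01). Stellate cell and fibroblast, cholangiocyte, neutrophil and platelet lists had fewer than 3 measured members in every comparison.

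The series is about the microRNA miR-342, whose gene lies within Evl, which encodes an actin regulator of the Ena/VASP family. In GRCm38, Evl spans chromosome 12, 108554720 to 108688516, and Mir342 (108658620 to 108658718) lies inside it and overlaps 0 of its exons. Mir342 itself was not in the table, and 3' counts of Evl measure its polyadenylated host transcript. Evl stood at 185 scaled CPM in RPM (161 to 212), 127 in KC (63.6 to 228, from 11 UMIs), 116 in cDC1 (95.9 to 139), 99.8 in cDC2 (85.6 to 116), 96.2 in B cells (77.8 to 118) and 8.48 in LSEC (4.64 to 14.2). The host gene was thus 15.0-fold higher in KC than in LSEC (6.17 to 35.6), while the KC interval overlapped those of RPM and of the other splenic libraries. No share of the other libraries was taken off the 11 KC UMIs, so the size of this fold is uncertain. Of 9 measured members of the list of Evl and microRNA machinery genes, 1, Evl, was higher in KC and 2 in LSEC, with the argonaute gene Ago3 at 19.3-fold (3.45 to 766), from 1 UMI against 370.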

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

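The KC library limits the comparisons that use it, and 1 library per population leaves animal and batch differences unmeasured. The alternatives KC less background, the same with total counts, KC less LSEC share and leaving out the KC library were chosen after the data were seen. The cause was not tested for any change below unless said. List medians are given as turned only where they lay among the lowest or highest 2.5% of random lists. With total counts per library, genes higher in KC than in RPM numbered 117, genes higher in RPM than in KC 64, genes higher in LSEC than in KC 197 and genes highest in KC 44. With no count minimum, genes higher in KC than in RPM numbered 226, genes higher in KC than in LSEC 579 and genes highest in KC 60. The Spearman correlation across genes of KC and RPM was then 0.688 and with at least 30 counts 0.595. The Spearman correlation across genes of cDC1 and cDC2 was 0.844 and 0.788, the Spearman correlation across genes of KC and LSEC 0.634 and 0.503, and the Spearman correlation across genes of RPM and cDC2 0.789 and 0.556. With at least 30 counts, genes higher in KC than in RPM numbered 13, in cDC1 than in cDC2 134, in KC than in LSEC 68 and genes higher in RPM than in cDC2 623, and genes highest in B cells 116, in cDC1 33, in RPM 90 and in KC 11. Medians that turned with at least 30 counts were cDC1, KC over RPM (-0.30), interferon-stimulated, KC over RPM (-0.47), scavenger receptors, KC over RPM (-0.26), Fc and complement receptors, KC over LSEC (-0.66), lipid handling and LXR targets, KC over LSEC (-0.23), and sort antigens, RPM over cDC2 (-0.50). Thinned to the smallest library, genes higher in RPM than in KC numbered 55, in cDC1 than in cDC2 23, in cDC2 than in cDC1 25, in LSEC than in KC 155, in RPM than in cDC2 148 and in cDC2 than in RPM 46. Correlations in that order of pairs (KC and RPM, cDC1 and cDC2, KC and LSEC, RPM and cDC2) were 0.255, 0.579, -0.0211 and 0.191. Genes highest in B cells numbered 19, in cDC1 2, in cDC2 4, in RPM 19 and in LSEC 85, and interferon-stimulated, KC over RPM was -0.59. With 99% intervals, genes higher in RPM than in KC numbered 111 and in LSEC than in KC 207. With KC less background, which took off 0.511% of the other libraries and left 52.7% of its UMIs, genes higher in KC than in RPM numbered 37, in RPM than in KC 794, in KC than in LSEC 144 and in LSEC than in KC 977. This share exceeds what was counted for H2-Aa (186 UMIs in KC, 247 expected), Cd74 (684, 960.5) and Hba-a1 (36, 90.5), so medians of such lists are set by values of 0. An even share at this rate is itself argued against by 97 of 199 abundant genes whose upper limit lay below it, so these values do not show the direction without carry-over. Medians that turned against RPM were cDC1 (-0.49), pan-dendritic (-0.14), sinusoidal endothelial (-2.79), MHC class II presentation (-4.63), scavenger receptors (-0.51) and coagulation and vascular tone (-0.79). Against LSEC they were sort antigens (-4.04), cDC2 (-0.17), erythroid (-4.07), plasma cell (-0.76), MHC class II presentation, KC over LSEC (-3.26, over 10 members still measured), MHC class I presentation, KC over LSEC (-0.0102) and lysosome, KC over LSEC (-0.00763). Lists nearer their random lists also changed sign: plasma cell (-2.00), antiviral restriction (-0.34) and dissociation stress genes (-0.52) against RPM, and cell cycle (-2.51), lineage transcription factor (-1.26) and haem and iron genes (-0.21) against LSEC. With total counts as well, genes higher in KC than in RPM numbered 161 and genes highest in KC 110, with sinusoidal endothelial, KC over RPM at -2.89, MHC class II presentation, KC over RPM at -4.73, and sort antigens, KC over LSEC (-4.33), erythroid, KC over LSEC (-4.36) and MHC class II presentation, KC over LSEC (-3.31). With KC less LSEC share, genes higher in RPM than in KC numbered 280, sinusoidal endothelial, KC over RPM was -2.79 and scavenger receptors, KC over RPM -0.36. The rate came from LSEC-restricted genes, so endothelial genes go to about 0 by construction. Without the KC library, genes highest in RPM numbered 309 and genes highest in LSEC 794. With DESeq2 size factors, all 14 main counts and 226 other values were labelled neither moved nor reversed. A change of sign near 0 did not alter the label. It occurred for dissociation stress genes in KC against RPM (0.02 and -0.02) and lineage transcription factors in cDC1 against cDC2 (-0.02 and 0.01). Total counts left 207 of the other values and moved 19. A prior count of 0.5 moved 1 median and one of 5 moved 3.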

Other observations

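The highest correlations across genes were between splenic libraries: cDC1 and cDC2 (0.821), B cells and cDC2 (0.709) and RPM and cDC2 (0.675). RPM and KC, macrophages of different organs, stood at 0.634, above KC and LSEC from the same liver (0.547) and RPM and LSEC (0.551). The order of RPM and KC above KC and LSEC held with all libraries thinned to 58547 UMIs (0.255 and -0.0211). With that thinning, the order of RPM and cDC2 above RPM and KC did not hold (0.191 and 0.255). Only UMI totals were matched, while reads per UMI were 2.32 in KC, 5.22 in RPM and 5.41 in LSEC. MHC class II genes took 7.69% of UMIs in cDC2, 7.10% in cDC1, 3.49% in B cells, 2.35% in KC, 1.43% in RPM and 0.265% in LSEC. The place of KC in this order is uncertain. B cell markers stood in KC at 0.511% of their UMIs in the other 5 libraries. By the same measure Cd74 stood at 0.364%, H2-Aa at 0.385%, H2-DMa at 0.495%, H2-Eb1 at 0.513%, H2-Ab1 at 0.667% and Ctss at 1.60%.

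The test of liver endothelial RNA in KC was written before the result, and that of an even share of all libraries after it. The interquartile range of the log2 KC to LSEC ratios of sinusoidal endothelial genes was 0.591, inside the 0.259 to 0.856 that counting noise in both libraries gives. Single genes departed from a common share: Cdh5 stood at 2.25% of its LSEC UMIs (1.36 to 3.52) and Dnase1l3 at 1.15% (1.03 to 1.28), against 0.528% for Clec4g (0.351 to 0.763). Over 75 LSEC-restricted genes the KC library held 612 UMIs, 0.523% of those in LSEC. If that share held for all LSEC UMIs, it would equal 12.7% of the KC library. Taking it off gene by gene removed 5989 UMIs and left 89.8%. An even share of all libraries at the rate that B cell markers show is argued against, since 97 of 199 abundant genes had an upper limit below it. Taken as sets, restricted markers of other libraries stood in KC at shares whose intervals overlapped. These were 0.498% for B cells (0.325 to 0.729), 0.769% for cDC1 (0.476 to 1.18), 0.673% for RPM (0.598 to 0.755) and 0.630% for LSEC (0.524 to 0.752). Members of a set differed. In the RPM set, Slc40a1, also among the genes shared by RPM and KC, had 90 UMIs in KC against 2367 in RPM. Hba-a1 had 36 against 16630. Naaa gave 18 of the 21 KC UMIs of the cDC1 set. The set shares thus need not measure carry-over alone. The overlap of these intervals does not show an even share, which would be a floor for every gene. Among the 199 abundant genes, the lowest 5% stood at or below 0.0926%. Rpl13 had 30 UMIs in KC of 21112 elsewhere (upper limit 0.203%) and Rps27 115 of 51286 (0.269%). These values argue against an even share as large as those of the restricted markers. A lower even share was not tested. How endothelial RNA reached KC, and whether Cdh5 and Dnase1l3 have a further source, stays open.

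The test of Kupffer cell RNA in LSEC was changed to markers with at least 10 UMIs after the result was seen, since only 1 had 100. The interquartile range of their log2 ratios was 3.02, against 0.285 to 0.935 from counting noise in both libraries, a range computed after the result was seen. This argues against Kupffer cell RNA as the whole source of macrophage transcripts in LSEC. A part of them from that source stays open. For hepatocyte RNA in both liver libraries, a test written before the result gave 1.98 over 14 markers with 29 UMIs in KC, inside the 0.727 to 2.03 of noise and between the bounds of 1 and 2 set for it, and leaves that source undecided.

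The test of B cell RNA in the splenic myeloid libraries was written before the result, and that of an even share after it. B cell markers spread over 3.00 in cDC1 and 2.78 in cDC2, which argues against B cell RNA as the whole source there, and over 1.23 in RPM, which leaves it undecided. Relative to endothelial markers, the share of 7 B cell markers was 2.84 times as large in cDC2, which argues against an even share of the pool. It was 2.30 times as large in RPM, where an even share stays undecided, and 1.56 times in cDC1. The 7 markers had low counts in all other libraries. They stood at 2.03% in cDC1, against 6.20% over all 13 markers, so the cDC1 ratio cannot decide. Expression by the myeloid cells themselves was not tested apart from these.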
